A study of Homo sapiens with 60 samples.

How the data were processed

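A549 RNA was made into directional mRNA libraries and sequenced with paired 100-base reads, per the labels' protocols, and how mRNA was selected is not given in the sources used here. The same protocols say that the plants were dried before extraction, which covers both gingers. The deposited table holds estimated counts per Ensembl gene, not normalised, per the values, which have 2 decimals and totals that differ between libraries. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 and the build GRCh38 (hg38), without saying what each step did. The annotation release and the strand setting of the counting are not given in the sources used here. Whether reads of overlapping and antisense genes were told apart is therefore not known. The sample labels give 0.1% DMSO for the vehicle and the series' design text gives 2%. The table has 60675 genes in 269 libraries, of which 60 carry labels of this series, and the other 209 columns were not used. Estimated counts were rounded to whole numbers. Symbols came from a current name table for 41209 identifiers and from GENCODE 29 for 15846, and 3620 identifiers (0.0579% of counts) had no name.

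Groups came from the sample labels. The design text says that extracts with an IC20 under 500 µg/mL were used at that concentration and at dilutions of it. The first number of the sample code differs between vehicle and extract libraries and cannot be told apart from treatment there, while high against low and ginger against ginger lie within one number. Codes of the vehicle libraries begin with A1 and those of wortmannin with 1. What the letter A marks is not given, and it cannot be told apart from treatment in wortmannin against vehicle. All 60 sample titles carry the words Second_BatchA, so the titles do not part vehicle from treated libraries by batch. Each comparison used edgeR 4.0.16 under R 4.3.3 (TMM normalisation, filterByExpr by group, robust quasi-likelihood fit) on all 60 libraries with 1 column per group and 40 residual degrees of freedom, so that all groups share one estimate of the spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. The filter left 17129 genes. The common biological coefficient of variation was 7.04%, and the estimated prior degrees of freedom had a median of 6.47. CPM values use TMM-adjusted library sizes. The standard error of a fold change is its size divided by the square root of F. In all, 0 libraries were identical, and the smallest chi-square per degree of freedom between replicates was 2.2, so none was counted as a duplicate.

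There were 30 lists of pathway genes and cell type markers, and the 26 with at least 5 tested genes were tested in 13 comparisons with camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg adjustment over the lists within a comparison). In 136 of the 338 list tests the adjusted p was under 0.05, and in 96 with an estimated correlation. Lists, designs, alternatives and the rule for named genes were fixed before the data were examined. For wortmannin and for each high dose that rule takes the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and all 3 treated libraries on one side of all 3 vehicle libraries. For the extracts such genes also had to be called in the same direction for high against low, with places filled by genes called only against vehicle where too few passed. For ginger against ginger it takes 4 rises and 4 falls. It adds the 4 members with the smallest p in the direction of each called list, at most 2 called members that moved the other way, and a panel of 19 genes, of which 18 passed the filter and TXNIP did not. Values of named genes are also given at the other doses of the same extract. Some genes that the rule takes are not reported here. Of the 30 lists, those of metallothioneins, PXR and CAR targets, blood cell markers, and fibroblast and endothelial markers had too few tested genes for camera and were counted only.

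Alternatives were the size factors of DESeq2 in edgeR, no filter on low counts, DESeq2 1.42.0, only the libraries of the 2 groups, a replicate block, and each library left out in turn. For lists they were the estimated correlation, fry, the size factors, the block and each replicate number left out. After the data were seen, the slope of log2 CPM on log2 transcript length in each library was added as a covariate, and fits without 3 libraries that lay far out on a length-related component were added. The length of a gene is that of its longest GENCODE 29 transcript, known for 99.3% of tested genes.

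The fit was tested on simulated data in which 200 genes were changed in the wortmannin libraries, with independent noise and no length gradient. Over 16726 genes, edgeR recovered 81.0% of 100 genes changed 1.5-fold and 90.0% of 100 genes changed 2-fold, with 9 other genes called. DESeq2 recovered 81.0% and 90.0% with 15 others. For a simulated ZF high group with no change edgeR called 0 genes. Camera called the changed list and 2 others, and 2 of these held a changed gene by chance. Counts are of reads without molecular identifiers, so precision covers counting and library spread only.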

Results

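RNA of A549 cells, an established human lung carcinoma line, was sequenced as mRNA libraries after 24 h of treatment. The 60 libraries form 20 groups of 3. They comprise a DMSO vehicle, wortmannin at 10 µM (an inhibitor of PI3-kinase that served as positive control), and hot-water extracts of 6 crude drugs at 3 doses each. Zingiberis Rhizoma Recens (ZRR, by its name fresh ginger), Zingiberis Rhizoma (ZR, dried ginger), Pinelliae Tuber (PT) and Zizyphi Fructus (ZF, jujube) were given at 500, 100 and 20 µg/mL. Scutellariae Radix (SR) was given at 230, 46 and 9.2 µg/mL and Coptidis Rhizoma (CR) at 130, 26 and 5.2 µg/mL. The high doses of SR and CR lie under 500 µg/mL, where the design text sets the IC20 as the dose. Call counts of SR and CR and those of the other extracts therefore belong to doses chosen in different ways. The libraries held 17420400 to 36479600 estimated counts each (totals to 6 digits), and 17129 genes were tested. Replicates of one group correlated at 0.982 or above on the log scale. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. All adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and all those for gene lists come from camera. Values after ± in log2 fold changes are standard errors, and those beside expression levels are SD with n = 3.

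**Figure D1:**
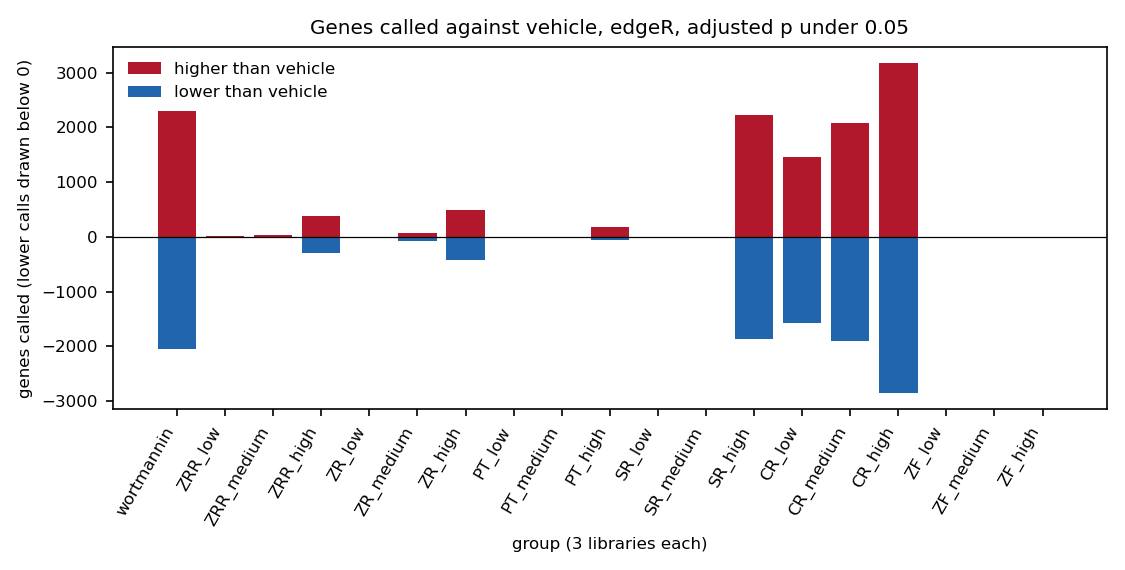
Number of genes called against vehicle in each treated group (3 libraries per group, edgeR, adjusted p under 0.05), with genes higher than vehicle above 0 and genes lower drawn below 0. CR at the high dose has 3167 higher and 2853 lower genes, and the 3 ZF groups have at most 2 called genes each.

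The first comparison asked what the positive control did. Wortmannin lowered integrated stress response genes and mitosis genes and raised cholesterol synthesis genes. Asparagine synthetase (ASNS) fell from 126 ± 2.9 to 40.4 ± 1.34 CPM (normalised read counts), a log2 fold change of -1.65 ± 0.06 (edgeR, adjusted p = 4.71e-27). PSAT1, an enzyme of serine synthesis, had a log2 fold change of -1.22 ± 0.04, the stanniocalcin STC2 one of -1.81 ± 0.08 and CHAC1, which degrades glutathione, one of -1.99 ± 0.12. In the list of integrated stress response genes, which ATF4 and CHOP drive, 0 of 26 rose and 23 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.42e-62). In the mitosis list 0 of 25 rose and 23 fell, or 0 and 24 adjusted over the list alone (camera adjusted p = 6.66e-45), with the kinases PLK1 at -0.66 ± 0.03 and AURKA at -0.66 ± 0.04. Among MYC and ribosome biogenesis genes 0 of 20 rose and 16 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.14e-13), including nucleolin (NCL) at -0.37 ± 0.04. Among cholesterol synthesis genes 16 of 24 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 2.9e-08), with the sterol reductase TM7SF2 at 1.18 ± 0.10 and the sterol oxidase MSMO1 at 0.57 ± 0.05. Of the FOXO targets, which rise when PI3-kinase signalling falls, 6 of 17 rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.00203, and adjusted p = 0.139 with an estimated correlation). PDK4, which restrains pyruvate oxidation, rose by 0.85 ± 0.09 and the insulin receptor substrate IRS2 by 0.29 ± 0.06. The growth factor IGF2 rose by 1.35 ± 0.13 and the secreted protease MMP7 by 1.14 ± 0.11, while the stress-induced gene HMOX1 fell by 0.67 ± 0.07 on the log2 scale. In total 4340 genes were called, 2295 higher and 2045 lower, of which 208 rose and 50 fell at least 2-fold. The count was 6665 with the length slope as a covariate.

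Both gingers at 500 µg/mL raised targets of the aryl hydrocarbon receptor (AHR) and of the integrated stress response and lowered heat shock and matrix genes. The cytochrome P450 gene CYP1B1 rose from 54.8 ± 1.54 CPM in vehicle to 124 ± 1.07 CPM with fresh ginger (log2 fold change 1.18 ± 0.06, edgeR adjusted p = 6.04e-19) and to 149 ± 10.5 CPM with dried ginger (1.44 ± 0.06, adjusted p = 1.08e-22). CYP1A1, another xenobiotic-metabolising P450, rose by 1.73 ± 0.22 and 2.10 ± 0.21. In the AHR list 4 of 7 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.81e-19) with fresh ginger, and 4 of 7 rose and 0 fell, or 5 and 0 adjusted over the list alone (adjusted p = 8.7e-34) with dried ginger. In the integrated stress response list 19 of 26 rose and 0 fell, or 21 and 0 adjusted over the list alone (camera adjusted p = 6.57e-77) with fresh ginger, and 17 of 26 rose and 0 fell, or 21 and 1 adjusted over the list alone (adjusted p = 2.29e-57) with dried ginger. TRIB3, a pseudokinase, rose by 1.03 ± 0.06 and 0.88 ± 0.06. Among heat shock genes 0 of 16 rose and 9 fell, or 0 and 11 adjusted over the list alone (camera adjusted p = 1.75e-15) with fresh ginger and 0 of 16 rose and 6 fell, or 0 and 8 adjusted over the list alone (adjusted p = 2.64e-09) with dried ginger, and HSPA1A was at -0.44 ± 0.07 and -0.33 ± 0.07. Among TGF-beta and matrix genes 0 of 22 rose and 11 fell, or 0 and 13 adjusted over the list alone (camera adjusted p = 1.31e-30) with fresh ginger, including the collagen COL1A1 at -0.75 ± 0.07. With dried ginger 1 of 22 rose and 7 fell, or 2 and 10 adjusted over the list alone (camera adjusted p = 2.64e-09). The fibrinogen gene FGB, of the liver marker list, fell by 0.37 ± 0.05 and 0.75 ± 0.05 on the log2 scale, and the nuclear receptor NR4A1 by 1.06 ± 0.06 and 1.32 ± 0.06.

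Genes of NF-kB inflammation rose with dried ginger at this dose, where 14 of 17 rose and 0 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 1.55e-53). The chemokine CXCL8 rose from 0.877 ± 0.282 to 4.69 ± 0.591 CPM (log2 fold change 2.38 ± 0.21, edgeR adjusted p = 7.99e-12), and CCL2, a monocyte chemokine, rose by 1.34 ± 0.14. With fresh ginger 2 of 17 rose and 1 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0477, and adjusted p = 0.0745 with an estimated correlation), a call that also ended without replicate 1 of each group (adjusted p = 0.206), without replicate 2 (0.0958) and with a transcript-length slope as a covariate (0.0974), in a range of 0.00153 to 0.206 over the alternatives. CXCL2, a neutrophil chemokine, rose by 0.83 ± 0.16 and PTGS2, a prostaglandin synthase, fell by 0.56 ± 0.13 on the log2 scale. Of the antioxidant NRF2 targets, 8 of 20 rose and 0 fell, or 11 and 0 adjusted over the list alone (camera adjusted p = 2.81e-11) with fresh ginger and 2 of 20 rose and 0 fell, or 3 and 0 adjusted over the list alone (adjusted p = 0.0026, and adjusted p = 0.153 with an estimated correlation) with dried ginger, with HMOX1 at 0.40 ± 0.07 and 0.35 ± 0.07. Among cholesterol synthesis genes 8 of 24 rose and 0 fell, or 10 and 1 adjusted over the list alone (camera adjusted p = 2.4e-09) with fresh ginger, and the sterol regulator INSIG1 was at 0.48 ± 0.05. The fold changes at this dose correlated with transcript length at -0.326 for fresh and -0.205 for dried ginger (Spearman, across genes). Fresh ginger gave 690 calls (386 higher and 304 lower) and dried ginger 916 (498 higher and 418 lower). The fresh ginger count was 426 without ZRR high replicate 1, 455 without ZRR high replicate 2, and 427 without vehicle replicate 1 or vehicle replicate 2, and 1611 with that covariate, of which 690 were among the 690. It was 1075 with only the libraries concerned, and that of dried ginger 2062 with the length slope as a covariate.

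Within each ginger, the high dose was also set against the low dose, which shares the first number of the sample code. Integrated stress response genes rose in both: 16 of 26 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 3.05e-49) with fresh ginger, and 16 of 26 rose and 0 fell, or 19 and 0 adjusted over the list alone (adjusted p = 6.13e-51) with dried ginger. STC2 rose by 0.96 ± 0.07 and 1.14 ± 0.07 (edgeR adjusted p = 3.27e-15 and 3.17e-18), and CYP1B1 by 1.09 ± 0.06 and 1.29 ± 0.06. In the NF-kB list 15 of 17 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.12e-42) with dried ginger, with CXCL8 at 1.75 ± 0.20, while for fresh ginger 3 of 17 rose and 0 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.139). The collagen COL1A1 fell by 0.73 ± 0.07 and 0.63 ± 0.07 on the log2 scale and FGB by 0.43 ± 0.05 and 0.78 ± 0.05. Fresh ginger had 715 calls (423 higher and 292 lower) and dried ginger 795 (421 higher and 374 lower). Leaving out ZRR low replicate 2 gave 419, ZRR high replicate 1 gave 460 and ZRR high replicate 3 gave 436. For dried ginger, leaving out ZR high replicate 1 gave 518, and with only the 6 libraries concerned the counts were 114 and 64. Fold changes of high against low rose with transcript length, with Spearman correlations of 0.431 for fresh and 0.39 for dried ginger across 11306 genes, which are not independent replicates. With the length slope as a covariate the counts were 1459 and 1462.

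At 100 µg/mL CYP1B1 rose by 0.36 ± 0.06 with fresh and 0.48 ± 0.06 with dried ginger (edgeR adjusted p = 0.00174 and 1.41e-05), and TRIB3 by 0.38 ± 0.07 and 0.35 ± 0.06. Fresh ginger had 48 calls (25 higher and 23 lower) and dried ginger 158 (76 higher and 82 lower). At 20 µg/mL the counts were 19 and 1, and the 1 gene called for dried ginger was CMTM8 at 0.56 ± 0.10, named after its value was seen. Fold changes against vehicle fell with transcript length in these groups, with Spearman correlations of -0.643 (fresh, medium), -0.678 (dried, medium), -0.655 (fresh, low) and -0.619 (dried, low) across 11306 genes, which are not independent replicates. With the length slope as a covariate, 37 of the 48 and 65 of the 158 medium-dose calls remained, of 97 and 114 in all. The fresh medium-dose count was 1031 without the filter, 370 without the 3 libraries far out on the length component, 123 with DESeq2 and 2243 with only the libraries concerned, and the dried one 2219 without the filter, 2786 without the 3 libraries far out on the length component, 741 with DESeq2 and 2824 with only the libraries concerned. Leaving out 1 library in turn moved the counts at the medium dose over ranges of 10 to 37 for fresh and 24 to 427 for dried ginger, the lowest without vehicle replicate 1 in both. The highest for dried ginger was 427, without ZR medium replicate 2. At the low dose the range was 0 to 135 for fresh ginger, with 0 calls without vehicle replicate 1 or 2 and 135 without ZRR low replicate 1, and 0 for dried ginger without any 1 of its 6 libraries. Other low-dose counts were 1328 without the filter, 76 with the length slope as a covariate, 105 with DESeq2 and 0 with only the libraries concerned for fresh ginger, and 426 without the filter, 0 with the replicate block, 5 with the length slope as a covariate, 0 without the 3 libraries far out on the length component, 6 with DESeq2 and 0 with only the libraries concerned for dried ginger.

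The gingers, named for the fresh and the dried rhizome, were then set against each other at matched doses. At the high dose, genes of NF-kB inflammation were lower with fresh than with dried ginger. CXCL8 was at 1.27 ± 0.377 CPM with fresh and 4.69 ± 0.591 CPM with dried ginger, a log2 difference of -1.90 ± 0.21 (edgeR adjusted p = 2.76e-08). CCL2 differed by -1.04 ± 0.13 and the cytokine IL32 by -0.94 ± 0.15. Of 17 tested genes of the list, 12 were lower and 0 higher. The keratin KRT4 was higher with fresh ginger by 0.72 ± 0.07 and DDC, which makes dopamine and serotonin, by 0.62 ± 0.09. In all 122 genes differed, 55 higher and 67 lower with fresh ginger, and 73 did without ZRR high replicate 1. At the medium dose KRT4 alone was called, at 0.36 ± 0.07 (edgeR adjusted p = 0.0483), and edgeR called 0 genes without ZRR medium replicate 1, 2 or 3 or ZR medium replicate 2 or 3. At the low dose edgeR called 0 genes, 732 had an unadjusted p under 0.05, and DESeq2 called 0, while edgeR without ZR low replicate 3 called 3. The high-dose count was 353 with the length slope as a covariate. The medium-dose count was 0 with the size factors of DESeq2, 64 without the filter, 0 with the replicate block, 6 with the length slope as a covariate and 2 with DESeq2, and the low-dose count 100 without the filter, 3 with the length slope as a covariate, 3 without the 3 libraries far out on the length component and 1 with only the libraries concerned. Spearman correlations of these differences with transcript length were -0.188, 0.352 and -0.298 across genes at the high, medium and low dose.

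The dose effect itself, high against low, differed between the gingers for 24 genes, 14 with a more positive change in fresh ginger and 10 with a more negative one. The difference of fresh minus dried ginger was -0.47 ± 0.07 for the chemokine CXCL5 (edgeR adjusted p = 0.00117) and -1.04 ± 0.20 for CCL2 (adjusted p = 0.00661), both named after their values were seen. The count was 12 without ZRR high replicate 1 or without ZR high replicate 2, 14 without ZRR high replicate 2 or without ZR low replicate 2, and 13 without replicate 3 of ZRR high or of ZRR low. It was 112 without the filter, 152 with the length slope as a covariate and 37 with DESeq2, and 0 in a fit of the 12 libraries alone (523 at an unadjusted p under 0.05). Of 100 splits of the libraries drawn within each ginger, the real one included, 23 gave at least 24 genes, so chance is not excluded. The difference of fold changes, fresh minus dried, had a Spearman correlation with transcript length of 0.0715 across genes.

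**Figure D2:**
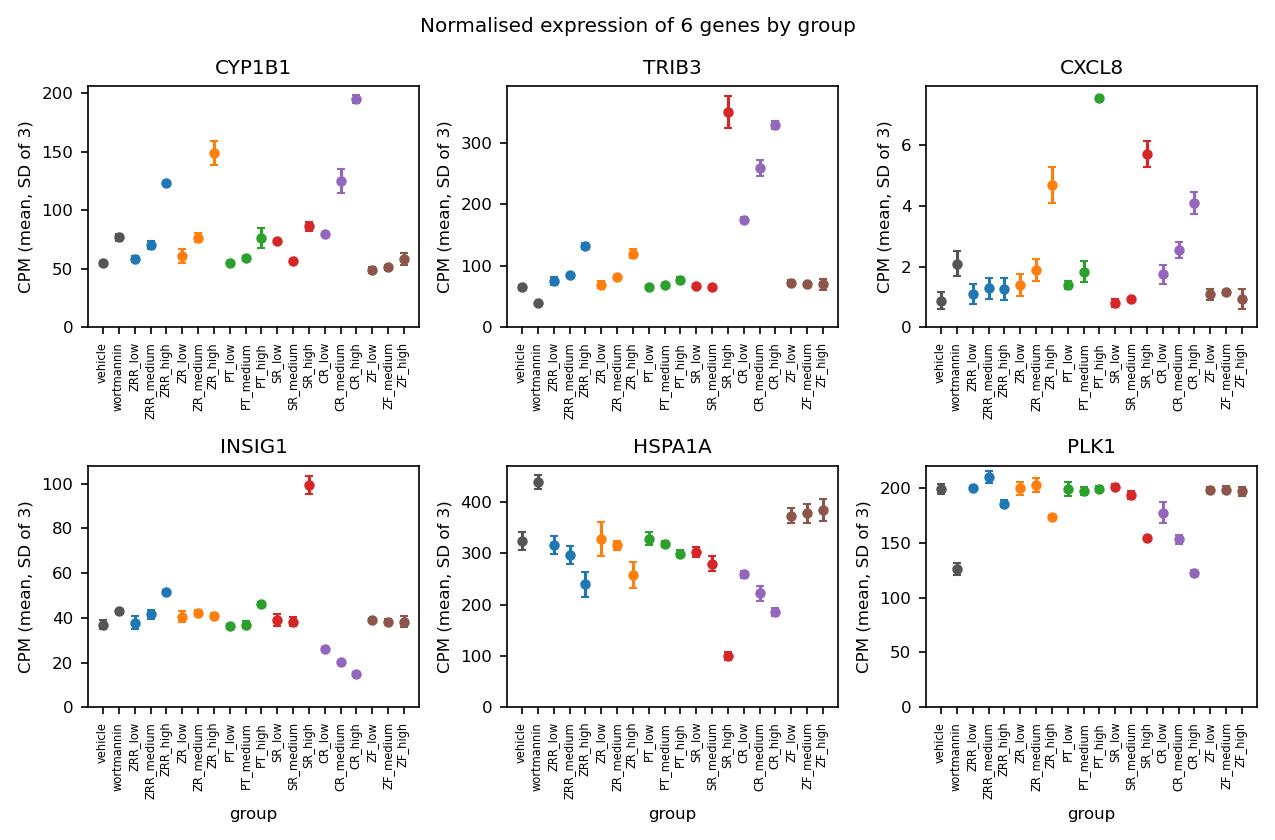
Normalised expression (CPM, mean with SD of 3 libraries) of 6 genes in the 20 groups, on linear axes that start at 0. CYP1B1 is at 54.8 CPM in vehicle and 149 CPM with the high dose of dried ginger, and HSPA1A is at 324 CPM in vehicle and 99.5 CPM with the high dose of SR.

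PT at 500 µg/mL raised chemokines and other NF-kB genes. CXCL8 rose from 0.877 ± 0.282 to 7.57 ± 0.0361 CPM (log2 fold change 3.08 ± 0.20, edgeR adjusted p = 1.66e-15), CXCL1 by 2.85 ± 0.20, CXCL5 by 1.09 ± 0.05, CCL2 by 1.38 ± 0.14 and the cytokine IL32 by 1.33 ± 0.14. In the NF-kB list 14 of 17 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.32e-78), and 14 of 17 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 1.49e-84) against the low dose. Among cholesterol synthesis genes 8 of 24 rose and 0 fell, or 14 and 0 adjusted over the list alone (camera adjusted p = 3.45e-12), including INSIG1 at 0.32 ± 0.05 and the mevalonate kinase MVK at 0.40 ± 0.07. The complement gene C3 rose by 0.91 ± 0.09, and ID4, an inhibitor of DNA binding, fell by 0.83 ± 0.12 on the log2 scale. In the AHR list 2 of 7 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 1.48e-05), with CYP1B1 at 0.48 ± 0.06. The autophagy receptor SQSTM1 rose by 0.30 ± 0.05, and in the autophagy and lysosome list 3 of 28 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.00282). The nuclear respiratory chain list was called higher although 0 of 29 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000493, and adjusted p = 0.681 with an estimated correlation), and with the length slope in camera the adjusted p was 0.23 in the other direction. Without replicate 2 of each group it was 0.212, in a range of 7.88e-05 to 0.681 over the alternatives. Fold changes against vehicle fell with transcript length here too (Spearman correlation -0.586 across genes, and -0.552 for high against low). There were 240 calls against vehicle, 184 higher and 56 lower, and 94 against the low dose, 68 higher and 26 lower. DESeq2 gave 331 against vehicle, 215 higher and 116 lower. Against vehicle there were 69, 63 and 64 calls without vehicle replicate 1, vehicle replicate 2 and PT high replicate 2, and the count was 1343 without the filter, 940 without the 3 libraries far out on the length component and 26 with only the libraries concerned. With the length slope as a covariate 175 of the 240 remained. Against the low dose there were 57 without PT low replicate 1 or PT low replicate 2 and 53 without PT high replicate 2, and the count was 729 without the filter, 182 with the length slope as a covariate, 237 without the 3 libraries far out on the length component and 26 with only the libraries concerned.

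At 100 µg/mL PT gave 3 calls, named after their values were seen. CXCL5 was higher by 0.32 ± 0.05, ATOH8, a transcription factor, fell by 0.68 ± 0.10 on the log2 scale and ID4 fell by 0.60 ± 0.12 (edgeR adjusted p = 0.00107, 0.000517 and 0.0439). There was 1 call without vehicle replicate 1 or without PT medium replicate 2. At 20 µg/mL edgeR called 0 genes, 557 had an unadjusted p under 0.05, and DESeq2 called 2. The count at 100 µg/mL was 102 without the filter, 23 with the length slope as a covariate, 7 without the 3 libraries far out on the length component, 7 with DESeq2 and 7 with only the libraries concerned, and at 20 µg/mL 70 without the filter and 1 with only the libraries concerned.

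SR at 230 µg/mL raised stress, lipid and inflammatory genes and lowered cytosolic chaperones. DDIT3 (CHOP), a stress-induced transcription factor, rose from 8.42 ± 1.13 to 49 ± 3.89 CPM (log2 fold change 2.55 ± 0.12, edgeR adjusted p = 9.51e-22). TRIB3 rose by 2.43 ± 0.07 and STC2 by 2.20 ± 0.07, and in the integrated stress response list 23 of 26 rose and 0 fell, or 24 and 0 adjusted over the list alone (camera adjusted p = 1.09e-121). In the unfolded protein response list 14 of 18 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.97e-21), among them HERPUD1, of protein disposal, at 1.27 ± 0.06 and the chaperone HSPA5 at 0.70 ± 0.05. Among heat shock genes 0 of 16 rose and 15 fell, with the same counts adjusted over the list alone (camera adjusted p = 7.95e-64), with HSPA1A going from 324 ± 18.4 to 99.5 ± 8.25 CPM and HSPA8 at -0.97 ± 0.04. Among cholesterol synthesis genes 22 of 24 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 4.92e-54), including the sterol regulator INSIG1 at 1.43 ± 0.05. Of the fatty acid synthesis genes 9 of 12 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 6.69e-16), with the desaturase SCD at 0.99 ± 0.09 and the acyltransferase GPAM at -0.33 ± 0.09. In the NF-kB list 15 of 17 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 9e-31), with CXCL8 at 2.67 ± 0.21, and among immediate early genes 19 of 21 rose and 0 fell, or 20 and 0 adjusted over the list alone (adjusted p = 6.86e-41), with the transcription factor EGR1 at 2.62 ± 0.18. Of the p53 targets 14 of 23 rose and 0 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 2.93e-11), including GDF15, a secreted growth factor, at 1.60 ± 0.09. In the DNA replication list 0 of 26 rose and 18 fell, or 0 and 19 adjusted over the list alone (camera adjusted p = 2.9e-16) and in the mitosis list 0 of 25 rose and 21 fell, with the same counts adjusted over the list alone (adjusted p = 6.08e-19), with the helicase subunit MCM6 at -0.50 ± 0.03 and AURKA at -0.51 ± 0.04. There were 4101 calls against vehicle (2232 higher and 1869 lower) and 3498 against the low dose (1894 higher and 1604 lower). Mitochondrial rRNA made up 3.24 ± 0.18% of counts at this dose and 2.44 ± 0.096% in vehicle. The count against the low dose was 5433 with the length slope as a covariate. Fold changes correlated with transcript length at -0.26 against vehicle and -0.028 against the low dose (Spearman, across genes).

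At lower doses SR changed few genes. At 46 µg/mL edgeR called 0 genes, 722 had an unadjusted p under 0.05, and DESeq2 called 3, while edgeR without vehicle replicate 3 called 1. TRIB3 was at 0.01 ± 0.07 there, and at 2.43 ± 0.07 at the high dose. At 9.2 µg/mL, CYP1B1 was the 1 gene called, at 0.42 ± 0.06 (edgeR adjusted p = 0.000482), named after its value was seen. At the higher dose of 46 µg/mL CYP1B1 was at 0.06 ± 0.06 and was not called. The count at 46 µg/mL was 59 without the filter, 12 with the length slope as a covariate and 3 with only the libraries concerned, and at 9.2 µg/mL 148 without the filter, 6 with the length slope as a covariate, 2 without the 3 libraries far out on the length component, 5 with DESeq2 and 4 with only the libraries concerned.

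CR changed genes of stress signalling, sterol synthesis and cell division, with calls at all 3 doses. STC2 rose by 2.59 ± 0.07 at 130 µg/mL, 2.19 ± 0.07 at 26 µg/mL and 1.69 ± 0.07 at 5.2 µg/mL (edgeR adjusted p = 3.44e-33, 2.69e-30 and 2.38e-25). CYP1A1 rose by 2.87 ± 0.20, 2.03 ± 0.21 and 1.04 ± 0.23. In the integrated stress response list at the high dose 22 of 26 rose and 2 fell, or 23 and 2 adjusted over the list alone (camera adjusted p = 1.1e-81), and the members that fell were the amino acid transporter SLC7A5 at -0.18 ± 0.06 and the cysteine synthesis enzyme CTH at -0.36 ± 0.14. Among cholesterol synthesis genes 1 of 24 rose and 22 fell, with the same counts adjusted over the list alone (camera adjusted p = 6.85e-32), with INSIG1 at -1.31 ± 0.06, and TM7SF2 rose by 0.29 ± 0.11. In the mitosis list 0 of 25 rose and 24 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.87e-41) and in the DNA replication list 0 of 26 rose and 24 fell, with the same counts adjusted over the list alone (adjusted p = 5.12e-27), including RRM2, a ribonucleotide reductase subunit, at -0.96 ± 0.03. Of the AHR targets 6 of 7 rose and 0 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 1.34e-15), and of the NF-kB genes 13 of 17 rose and 1 fell, or 14 and 1 adjusted over the list alone (adjusted p = 2.29e-14), where PTGS2 fell by 0.37 ± 0.12 on the log2 scale. In the TGF-beta and matrix list 8 of 22 rose and 3 fell, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.00719, and adjusted p = 0.151 with an estimated correlation). The fibrinogen gene FGB fell by 1.77 ± 0.05 and the neuronal pentraxin NPTX1 by 1.82 ± 0.09 on the log2 scale. NIBAN1, a stress-responsive gene, rose by 3.22 ± 0.14 and GREM1, a BMP antagonist, by 3.04 ± 0.12. There were 6020, 3979 and 3024 calls at the high, medium and low dose, and 4357 for high against low (2250 higher and 2107 lower). Over the alternatives the adjusted p of these weaker calls ranged from 7.5e-05 to 0.127 for SLC7A5, 0.0189 to 0.167 for CTH, 0.0185 to 0.214 for TM7SF2 and 0.000266 to 0.0933 for PTGS2. Without vehicle replicate 1 and without CR high replicate 1 it was 0.127 and 0.0559 for SLC7A5 and 0.214 and 0.175 for TM7SF2, which DESeq2 left at 0.0558. For PTGS2 it was 0.0933 without vehicle replicate 3 and 0.0838 without CR high replicate 2, and for CTH it passed 0.05 with DESeq2 (0.0532) and without each of the 6 libraries except vehicle replicate 3. The low-dose count was 1277 without vehicle replicate 1, 1670 without vehicle replicate 2 and 1297 without CR low replicate 3, and with the length slope as a covariate 1282 of the 3024 remained, of 2254. The low-dose count was also 4551 without the 3 libraries far out on the length component. Fold changes against vehicle correlated with transcript length at -0.149, -0.389 and -0.585 at the high, medium and low dose, and those of high against low at 0.359 (Spearman, across genes).

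Mitochondrial RNA moved at every CR dose. The mitochondrial rRNAs made up 6.88 ± 0.4% of counts at the high, 11.9 ± 0.64% at the medium and 10.2 ± 1.1% at the low dose, beside 2.44 ± 0.096% in vehicle. MT-RNR1, the small-subunit rRNA, rose by 3.86 ± 0.10, 4.57 ± 0.10 and 4.34 ± 0.10 on the log2 scale, and MT-RNR2, the large-subunit rRNA, by 1.04 ± 0.08, 2.02 ± 0.08 and 1.85 ± 0.08 (edgeR, the largest of the 6 adjusted p being 1.99e-15). Both were named after their values were seen. Of the 13 mRNAs encoded in mitochondria, 0 rose and 12 fell at the high dose, 3 rose and 10 fell at the medium dose and 4 rose and 6 fell at the low dose. The cytochrome oxidase gene MT-CO3 fell by 0.95 ± 0.12, 1.46 ± 0.13 and 1.17 ± 0.12 at the high, medium and low dose. MT-CYB, of cytochrome b, was at -0.62 ± 0.11 at the high dose, 1.23 ± 0.11 at the medium and 1.77 ± 0.12 at the low dose, and MT-ND5, of complex I, at -0.84 ± 0.20, 0.83 ± 0.20 and 2.50 ± 0.21. The list test of these mRNAs at the high dose gave camera adjusted p = 1.34e-06, and adjusted p = 0.151 with an estimated correlation. Against the low dose 0 of 13 rose and 6 fell, or 0 and 8 adjusted over the list alone (camera adjusted p = 2.49e-12).

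**Figure D3:**
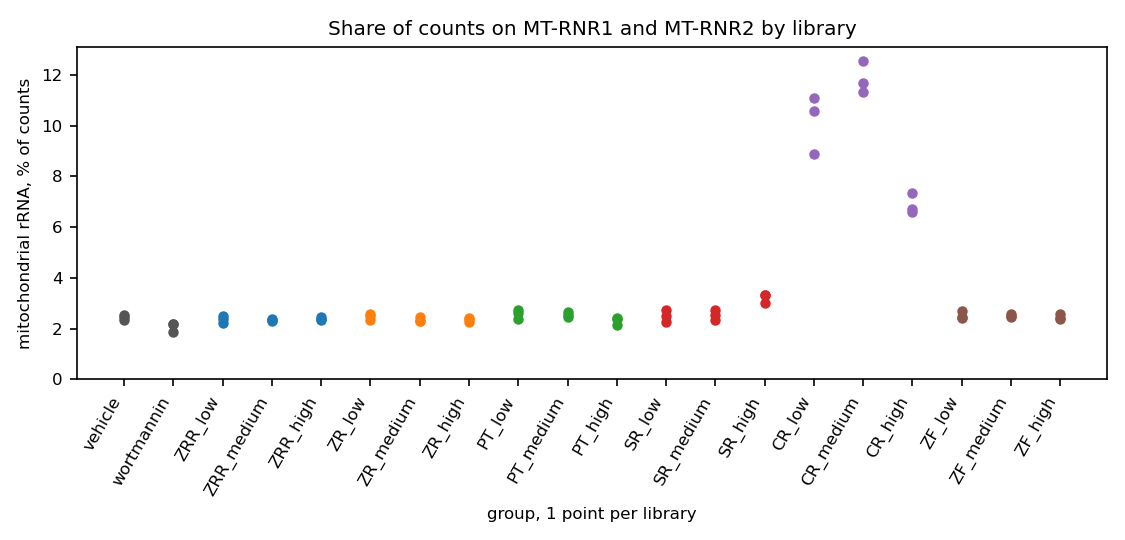
Share of each library's counts, in percent, on the mitochondrial rRNAs MT-RNR1 and MT-RNR2, 1 point per library and 3 libraries per group. The 9 CR libraries lie at 6.61% or above and the other 51 at 3.34% or below.

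ZF left nearly all genes uncalled. FBRSL1 was higher by 0.31 ± 0.05, 0.30 ± 0.05 and 0.30 ± 0.05 at the high, medium and low dose (edgeR adjusted p = 0.0126, 0.022 and 0.0278). AMH, of anti-Müllerian hormone, was higher at the medium dose by 0.57 ± 0.11 and CMTM8 at the low dose by 0.54 ± 0.10, all named after their values were seen. No other gene was called by edgeR at these doses, and DESeq2 called 37, 7 and 19. The 3 doses share the vehicle libraries, and edgeR called 0 genes without vehicle replicate 1 at each dose. FBRSL1, AMH and CMTM8 were also called higher in the mean of all low doses, at 0.26 ± 0.04, 0.40 ± 0.09 and 0.44 ± 0.08. Other extracts had calls of these genes against the same vehicle libraries. FBRSL1 was called with PT high (0.29 ± 0.05) and AMH with ZRR high (0.44 ± 0.11). CMTM8 was called with ZRR high (0.38 ± 0.11), PT high (0.37 ± 0.10) and ZR low (0.56 ± 0.10). CYP1B1 was at 0.09 ± 0.06 and CXCL8 at 0.06 ± 0.26 in log2 fold change at the high dose, neither called. In the heat shock list 0 of 16 rose and 0 fell, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.00108, and adjusted p = 0.476 with an estimated correlation). The nuclear respiratory chain list, where 0 of 29 rose and 0 fell, with the same counts adjusted over the list alone, had camera adjusted p = 0.00108, and adjusted p = 0.723 with an estimated correlation, and adjusted p = 0.209 in the other direction with the length slope and 0.748, also in the other direction, without replicate 2 of each group. Its range over the alternatives was 9.64e-06 to 0.748. For high against low ZF edgeR called 0 genes, 397 had an unadjusted p under 0.05, and DESeq2 called 0. Counts against vehicle were 476 without the filter, 17 with the length slope as a covariate, 2 without the 3 libraries far out on the length component and 0 with only the libraries concerned at the high dose, 225 without the filter, 10 with the length slope as a covariate and 8 with only the libraries concerned at the medium dose, and 507 without the filter, 1 with the replicate block, 19 with the length slope as a covariate, 10 without the 3 libraries far out on the length component and 1 with only the libraries concerned at the low dose. For high against low the count was 43 without the filter and 3 with the length slope as a covariate. Fold changes of ZF correlated with transcript length at -0.591, -0.533 and -0.588 against vehicle at the high, medium and low dose and at 0.0222 for high against low.

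The mean of the 6 low-dose groups was set against vehicle to look for a shift shared by extract libraries, whose first code number differs from that of the vehicle. Its smallest adjusted p-values were those of MT-RNR1, CHAC1, TRIB3 and DDIT4, named after their values were seen. MT-RNR1 was at 0.78 ± 0.07 and CHAC1 at 0.48 ± 0.07 (edgeR adjusted p = 7.98e-10 and 0.000303). TRIB3 was at 0.33 ± 0.05 and DDIT4 at 0.25 ± 0.04 (edgeR adjusted p = 0.000344 for both). CR had MT-RNR1 at 4.34 ± 0.10, CHAC1 at 1.83 ± 0.09 and TRIB3 at 1.43 ± 0.06 at its low dose. In the other 5 low-dose groups MT-RNR1 lay between 0.03 and 0.10, with no call by edgeR, CHAC1 between 0.08 and 0.42 and TRIB3 between 0.03 and 0.21. The mean gave 42 calls, 36 higher and 6 lower, and DESeq2 called 227, 140 higher and 87 lower. The edgeR count was 1287 without the filter and 127 with the length slope as a covariate, and 0 in a fit of the 21 libraries alone with the 18 extract libraries as 1 group (1782 at an unadjusted p under 0.05). Without vehicle replicate 1 there were 5 and without vehicle replicate 2 there were 8, while leaving out ZR low replicate 1 gave the highest count, 98. Other libraries that moved it were ZRR low replicate 1 (97), ZR low replicates 2 and 3 (79 and 27), CR low replicate 1 (72) and ZF low replicate 2 (85). The Spearman correlation of these fold changes with transcript length was -0.639 across genes.

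**Figure D4:**
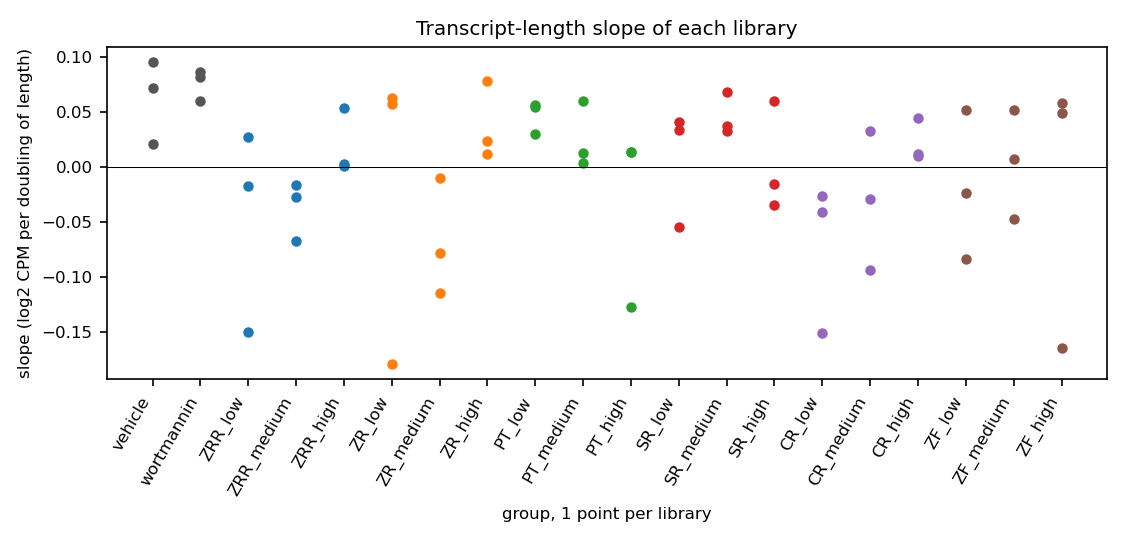
Slope of log2 CPM on log2 transcript length for each library, in log2 CPM per doubling of length, 1 point per library and 3 libraries per group. Vehicle libraries lie between 0.0205 and 0.0950, and CR low-dose libraries between -0.151 and -0.0263.

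Dose effects (high against low) were compared between extracts across all tested genes, over 21 pairs that include wortmannin against vehicle. Pearson's r across genes was 0.32 between dried ginger and CR, 0.25 between SR and CR and 0.23 between the gingers. Without replicate 3 of each group r was 0.11 between dried ginger and CR and 0.08 between the gingers, and without replicate 2 it was 0.16 between SR and CR and 0.07 between the gingers. For the 3 pairs in the first order it was 0.69, 0.47 and 0.66 among genes with a mean log2 CPM of at least 3, and 0.26, 0.27 and 0.19 over all genes with the length slope as a covariate. Over all genes r was lowest between dried ginger and PT (-0.17), PT and CR (-0.12) and fresh ginger and PT (-0.10). Spearman correlations of these 3 pairs were -0.14, -0.16 and -0.18, which reverses their order, and those of the first 3 pairs were 0.44, 0.33 and 0.39. Pearson's r of the 3 lowest pairs was -0.22, -0.23 and -0.34 among genes with a mean log2 CPM of at least 3. Among genes called in either comparison it was 0.43, 0.04 and 0.06, where the first 3 pairs had 0.63, 0.46 and 0.62. Dried ginger and PT were at 0.12 without replicate 3 and -0.06 without replicate 2, fresh ginger and PT at 0.05 without replicate 2, and PT and CR at -0.03 and -0.05 without replicates 2 and 3. With the length slope as a covariate these 3 pairs were at -0.08, 0.02 and -0.02. Fold changes of high against low correlated with transcript length at 0.431 for fresh ginger, 0.39 for dried ginger and 0.359 for CR. The Spearman correlations were -0.028 for SR and -0.552 for PT. The covariate was used over all genes only, so how far length enters r among genes with a mean log2 CPM of at least 3 was not tested. With wortmannin, r lay between -0.01 and 0.09 for the 6 extracts. Genes are not independent replicates, so no p-value is given.

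Positions in GENCODE 29 on GRCh38 are chromosome 2, 38066973 to 38109902 for CYP1B1 (ENSG00000138061), chromosome 15, 74719542 to 74725610 for CYP1A1 (ENSG00000140465) and chromosome 20, 362835 to 397559 for TRIB3 (ENSG00000101255). STC2 (ENSG00000113739) lies on chromosome 5, 173314713 to 173329503, CXCL8 (ENSG00000169429) on chromosome 4, 73740506 to 73743716, and HSPA1A (ENSG00000204389) on chromosome 6, 31815464 to 31817946. HSPA1A and HSPA1B are near-identical copies, so the counting could split their reads and each one's value is uncertain. Values are for whole genes.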

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

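Several tests in this part were chosen only after the results were seen. They were the correlation of the within-group component with transcript length and the count of CR libraries inside the vehicle slope range. So were the ZF comparison for mitochondrial rRNA and the rRNA shares of the 3 libraries far out on that component. The fits with the length slope and the splits in the fit of all 60 libraries were also chosen then. The count of all low-dose libraries inside the vehicle slope range and the test of RNAs without a poly-A tail address patterns already seen. Their predictions were set before their own outcome was known. The splits of 3 libraries against 3 were chosen before the results were seen.

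The dose effect differed between fresh and dried ginger for 24 genes by a test of the difference itself, 14 more positive and 10 more negative in fresh ginger. It was 12 without ZRR high replicate 1 or ZR high replicate 2, 13 without replicate 3 of ZRR high or ZRR low, and 14 without ZRR high replicate 2 or ZR low replicate 2. In the fit of all 60 libraries, 23 of 100 splits drawn within each ginger, the real one included, gave at least its 24 genes and the highest other gave 1933, so chance is not excluded. That split points to a structure among the samples, and a split that parts the doses in 1 ginger only carries that ginger's dose effect. A fit of the 12 libraries alone called 0 genes.

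NF-kB genes were lower with fresh than with dried ginger at the high dose in 12 of 17 cases. If differences in transcript length between libraries were the cause, fewer should remain with the length slope as a covariate, and 12 of 17 were lower with it. The covariate also raised the prior degrees of freedom from 6.47 to 38.3, so this count alone cannot decide. Among the genes called lower, the largest difference, of CXCL8, was -1.90 ± 0.21 without and -1.92 ± 0.19 with the covariate. The smallest, of TNFAIP2, was -0.25 ± 0.05 and -0.24 ± 0.03. The differences of these genes hardly changed in size, which argues against that cause for them. A difference between the preparations themselves stays open as a hypothesis, and what each extract carried was not measured here.

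Mitochondrial rRNA made up at least 6.61% of counts in each of the 9 CR libraries and at most 3.34% in the other 51. The ZF libraries share their first code number with CR and reached at most 2.7% where CR began at 6.61%, which argues against that number as the source. The 12 tested RNAs without a poly-A tail had a median log2 fold change of 0.24 in CR at the low dose (95% bootstrap interval 0.0585 to 0.521), below the rise of at least 1 that carry-over was taken to need. How mRNA was selected is not given, so whether these RNAs and mitochondrial rRNA would be carried over alike is not known. The test therefore cannot decide on carry-over. The 3 libraries farthest along the length-related component held 2.33%, 2.41% and 2.21% mitochondrial rRNA. An effect of CR may be a biological explanation, as a hypothesis found and tested on the same data, and reads shared with nuclear copies of mitochondrial genes were not separated.

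Short transcripts were higher than in vehicle in low-dose libraries, with a Spearman correlation of fold change and length of -0.639 across genes for the mean of the low doses. Within groups, the first component held 15.1% of the variance and its loading correlated with transcript length at -0.714 (GC content 0.19), so the same gradient separates replicates of one group. This is consistent with library preparation or RNA quality that differs between libraries. An effect common to the 6 extracts was taken to put all 18 low-dose libraries outside the vehicle range. That range was 0.0205 to 0.095 log2 CPM per doubling of length, and 9 lay inside it. These were 1 of 3 for ZRR, 2 of 3 for ZR and 3 of 3 for PT. For SR they were 2 of 3, for CR 0 of 3 and for ZF 1 of 3. A shared shift smaller than the spread between replicates need not do this, so the test cannot decide on a common effect. Mean slopes were 0.0624 in vehicle and 0.0759 with wortmannin. At the low dose they were -0.047 for ZRR, -0.0199 for ZR and 0.0464 for PT. Those of SR, CR and ZF were 0.00618, -0.0729 and -0.0187. The first code number differs between vehicle and extract libraries and cannot be told apart from such an effect. For CR, 0 of the 3 low-dose libraries lay inside the vehicle range, but CR was picked after this was seen. Mean slopes with CR were -0.0304 at the medium and 0.0219 at the high dose, nearer to vehicle as the dose rose. The libraries of ZRR medium (at most -0.0167) and ZR medium (at most -0.0103) also lay below the vehicle range. This count therefore cannot decide between an effect of CR and library preparation, and effects of single other extracts were not tested.

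For the mean of the low doses against vehicle, 7 of 100 splits of the 21 libraries in the fit of all 60 gave at least the real count of 42, and the highest other gave 7359, so chance is not excluded and that split points to a structure among the samples. These splits are no reference without change, since those that set CR low libraries apart carry the effect of CR, which had 3024 calls against vehicle. Splits of 3 libraries against 3 were fitted with only those libraries, and there are 10, too few for a share under 0.05. In 1 of the 10 splits, the real one included, as many genes were called or more, with real and highest other counts of 5505 and 2 for wortmannin against vehicle, 1075 and 165 for ZRR high against vehicle, 2243 and 2 for ZRR medium against vehicle, 1166 and 79 for ZR high against vehicle, 2824 and 0 for ZR medium against vehicle and 26 and 1 for PT high against vehicle. Further such pairs were 4691 and 1 for SR high against vehicle, 4 and 1 for SR low against vehicle, 7394 and 0 for CR high against vehicle, 4057 and 0 for CR medium against vehicle, 2559 and 1 for CR low against vehicle and 114 and 1 for ZRR high against ZRR low. Further such pairs were 64 and 0 for ZR high against ZR low, 26 and 0 for PT high against PT low, 3101 and 0 for SR high against SR low, 3950 and 1 for CR high against CR low and 161 and 39 for ZRR high against ZR high. In 2 of the 10 splits, the real one included, as many genes were called or more, with real and highest other counts of 7 and 775 for PT medium against vehicle, 8 and 92 for ZF medium against vehicle and 1 and 876 for ZF low against vehicle. In 3 of the 10 splits, the real one included, as many genes were called or more, with real and highest other counts of 1 and 1976 for ZRR low against ZR low. In 4 of the 10 splits, the real one included, as many genes were called or more, with real and highest other counts of 3 and 141 for SR medium against vehicle. In 7 of the 10 splits, the real one included, as many genes were called or more, with real and highest other counts of 1 and 522 for ZRR medium against ZR medium. In 9 of the 10 splits, the real one included, as many genes were called or more, with real and highest other counts of 1 and 57 for PT low against vehicle. In 10 of the 10 splits, the real one included, as many genes were called or more, with real and highest other counts of 0 and 0 for ZRR low against vehicle, 0 and 0 for ZR low against vehicle, 0 and 0 for ZF high against vehicle and 0 and 2976 for ZF high against ZF low. Splits that called several times the real count, in PT medium against vehicle, PT low against vehicle, SR medium against vehicle, ZF medium against vehicle, ZF low against vehicle, ZF high against ZF low, ZRR medium against ZR medium and ZRR low against ZR low, point to a structure among these samples.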

How the results depend on the processing

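The tests with the length slope as a covariate and those without 3 libraries were chosen only after the results were seen. Counts of called genes given for a setting moved by over 1.5 times or to or from 0, and the others under these settings lay within 1.5 times. Where no reason is given, the cause was not tested.

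The replicate block moved 3 values. They were 0 for ZR low against vehicle, 1 for ZF low against vehicle and 0 for ZRR medium against ZR medium. Same-numbered libraries did not deviate together on average. Their mean correlation was -0.0326, -0.0275 and -0.0136 within the first code numbers 2, 3 and 4. Between vehicle and wortmannin, whose codes differ by the letter A, it was -0.0879. Single pairs varied widely, from -0.664 to 0.537 within number 4. The replicate numbers were not treated as pairs, though these means cannot exclude that some libraries were handled together.

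With the size factors of DESeq2 in edgeR, the value that moved was 0 for ZRR medium against ZR medium. DESeq2 itself gave 123 for ZRR medium against vehicle, 105 for ZRR low against vehicle, 741 for ZR medium against vehicle, 6 for ZR low against vehicle, 7 for PT medium against vehicle and 2 for PT low against vehicle. Further values were 3 for SR medium against vehicle, 5 for SR low against vehicle, 37 for ZF high against vehicle, 7 for ZF medium against vehicle, 19 for ZF low against vehicle and 2 for ZRR medium against ZR medium. It also gave 37 for ginger dose interaction and 227 for all low doses against vehicle.

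Without the filter, the estimated prior degrees of freedom became infinite, where they were 6.47 with it. The counts became 1031 for ZRR medium against vehicle, 1328 for ZRR low against vehicle, 2219 for ZR medium against vehicle, 426 for ZR low against vehicle, 1343 for PT high against vehicle and 102 for PT medium against vehicle. Further values were 70 for PT low against vehicle, 59 for SR medium against vehicle, 148 for SR low against vehicle, 476 for ZF high against vehicle, 225 for ZF medium against vehicle and 507 for ZF low against vehicle. It also gave 729 for PT high against PT low, 43 for ZF high against ZF low, 64 for ZRR medium against ZR medium, 100 for ZRR low against ZR low, 112 for ginger dose interaction and 1287 for all low doses against vehicle.

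A fit with only the libraries of the 2 groups leaves fewer samples to estimate the spread, and whether this moved the counts was not tested. In such fits the counts were 1075 for ZRR high against vehicle, 2243 for ZRR medium against vehicle and 0 for ZRR low against vehicle. There were 2824 for ZR medium against vehicle, 0 for ZR low against vehicle and 26 for PT high against vehicle. Further values were 7 for PT medium against vehicle, 1 for PT low against vehicle, 3 for SR medium against vehicle, 4 for SR low against vehicle, 0 for ZF high against vehicle and 8 for ZF medium against vehicle. It also gave 1 for ZF low against vehicle, 114 for ZRR high against ZRR low, 64 for ZR high against ZR low, 26 for PT high against PT low and 1 for ZRR low against ZR low. Likewise, edgeR called 0 genes for the ginger dose interaction with its 12 libraries (523 at an unadjusted p under 0.05) and 0 for all low doses against vehicle with its 21, the extract libraries forming 1 group (1782).

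With the length slope as a covariate, where the prior degrees of freedom were 38.3, the counts were 6665 for wortmannin against vehicle, 1611 for ZRR high against vehicle, 97 for ZRR medium against vehicle, 76 for ZRR low against vehicle, 2062 for ZR high against vehicle and 5 for ZR low against vehicle. Further values were 23 for PT medium against vehicle, 12 for SR medium against vehicle, 6 for SR low against vehicle, 17 for ZF high against vehicle, 10 for ZF medium against vehicle and 19 for ZF low against vehicle. It also gave 1459 for ZRR high against ZRR low, 1462 for ZR high against ZR low, 182 for PT high against PT low, 5433 for SR high against SR low, 3 for ZF high against ZF low and 353 for ZRR high against ZR high. There were 6 for ZRR medium against ZR medium, 3 for ZRR low against ZR low, 152 for ginger dose interaction and 127 for all low doses against vehicle.

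Without ZR low replicate 3, ZF high replicate 2 and ZRR low replicate 2, which lay farthest along the length component, the counts were 370 for ZRR medium against vehicle, 2786 for ZR medium against vehicle, 0 for ZR low against vehicle, 940 for PT high against vehicle, 7 for PT medium against vehicle and 2 for SR low against vehicle. Further values were 4551 for CR low against vehicle, 2 for ZF high against vehicle, 10 for ZF low against vehicle, 237 for PT high against PT low and 3 for ZRR low against ZR low.

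The median r of the dose effects was 0.0383, and it was 0.0888 among genes with a mean log2 CPM of at least 3 and 0.137 among genes called in either comparison.

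Leaving out each library in turn gave 426 to 559 for ZRR high against vehicle, 10 to 37 for ZRR medium against vehicle, 0 to 135 for ZRR low against vehicle, 24 to 427 for ZR medium against vehicle and 0 in each case for ZR low against vehicle. The range was 63 to 239 for PT high against vehicle, 1 to 2 for PT medium against vehicle, 0 to 1 for SR medium against vehicle, 1277 to 2890 for CR low against vehicle and 0 to 7 for ZF high against vehicle. It was 0 to 2 for ZF medium against vehicle, 0 to 3 for ZF low against vehicle, 419 to 763 for ZRR high against ZRR low, 518 to 855 for ZR high against ZR low and 53 to 93 for PT high against PT low. Further ranges were 73 to 108 for ZRR high against ZR high, 0 to 1 for ZRR medium against ZR medium, 0 to 3 for ZRR low against ZR low, 12 to 27 for ginger dose interaction and 5 to 98 for all low doses against vehicle. The median r of the dose effects ranged from 0.0241 to 0.0587.

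The nuclear respiratory chain list turned in direction, with no call, in PT high (adjusted p = 0.23) and ZF high (0.209) against vehicle with the length slope in camera. It also turned in ZF high against vehicle without replicate 2 (0.748) and in ZR high against ZR low without replicate 3 (0.758). Over all alternatives the adjusted p ranged from 7.88e-05 to 0.681, 9.64e-06 to 0.748 and 4.02e-07 to 0.905 in these 3 comparisons.

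Of the named genes' calls, 0 turned in direction under any alternative, and 83 ended with only the libraries of the 2 groups, 51 without the filter, 8 with the block, 7 without the 3 libraries, 5 with DESeq2, 3 with the length slope and 3 with the size factors. Over all single libraries left out, calls ended in 230 cases. CXCL8 was at 0.88 CPM in vehicle, and whether depth limits the calls of such genes was not tested.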

Other observations

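The length slope and leaving out 3 libraries, which enter the ranges over alternatives given here, were chosen only after the results were seen, and the other tests in this part were planned.

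Further gene groups moved with wortmannin. Of the AHR targets 4 of 7 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00887), with CYP1B1 at 0.49 ± 0.06 (edgeR adjusted p = 3.76e-08). In the glycolysis list 2 of 14 rose and 10 fell, or 2 and 11 adjusted over the list alone (camera adjusted p = 0.000378, and adjusted p = 0.104 with an estimated correlation), with the phosphoglycerate mutase PGAM1 at -0.38 ± 0.05 and PGK1, an ATP-making kinase, at -0.32 ± 0.04. Among interferon response genes 5 of 17 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0218), with the RNA sensor RIGI at 0.47 ± 0.14. Markers of lung epithelium rose in part, where 3 of 8 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0137, and adjusted p = 0.0913 with an estimated correlation), with the lipid transporter ABCA3 at 0.92 ± 0.12 and the mucin MUC1 at 0.85 ± 0.21. In the list of epithelial keratins and junctions 3 of 11 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0119), with KRT19 at 0.70 ± 0.10. The metal-binding gene MT2A rose by 1.12 ± 0.13. Of NRF2 targets 1 of 20 rose and 8 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00887, and adjusted p = 0.192 with an estimated correlation), and the transporter ABCC3 rose by 0.70 ± 0.07.

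The liver marker list fell with both gingers, SR and CR at the high dose, and the called members were fibrinogen genes and, with CR, the iron carrier transferrin (TF) at -1.34 ± 0.42, whose edgeR adjusted p was 0.093 without vehicle replicate 3 and 0.0627 without CR high replicate 2, in a range of 0.00295 to 0.093 over the alternatives. Against vehicle 0 of 6 rose and 2 fell, or 0 and 4 adjusted over the list alone (camera adjusted p = 4.64e-08) with fresh ginger, 0 of 6 rose and 3 fell, or 0 and 4 adjusted over the list alone (adjusted p = 8.91e-23) with dried ginger, 0 of 6 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.0158, and adjusted p = 0.16 with an estimated correlation) with SR, where it was 0.0694 without replicate 3 of each group in a range of 4.53e-05 to 0.16 over the alternatives, and 0 of 6 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 3.73e-15) with CR. FGA, the fibrinogen alpha chain, fell by 0.41 ± 0.05, 0.70 ± 0.05, 0.35 ± 0.05 and 1.33 ± 0.05 on the log2 scale (edgeR adjusted p at most 4.69e-08). Against the low dose of the same extract, which shares no library with these controls, FGA fell by 0.41 ± 0.05, 0.65 ± 0.05, 0.36 ± 0.05 and 1.19 ± 0.05. The orphan nuclear receptor NR4A3 fell by 0.87 ± 0.15 with fresh ginger, 1.60 ± 0.15 with dried ginger and 2.18 ± 0.16 with CR, and the imprinted RNA H19 by 0.91 ± 0.08, 1.20 ± 0.08 and 1.75 ± 0.08.

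SR at the high dose raised further groups. In the hypoxia list 8 of 22 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00214), with the growth factor VEGFA at 0.80 ± 0.05 and the prolyl hydroxylase EGLN3 at -0.52 ± 0.10. In the autophagy and lysosome list 13 of 28 rose and 2 fell, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.00171), with SQSTM1 at 0.46 ± 0.05 and the sialidase NEU1 at 0.65 ± 0.08 (edgeR adjusted p = 5.41e-09). With CR at the high dose, of the p53 targets 16 of 23 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 6.99e-10), with the cell cycle inhibitor CDKN1A at 0.84 ± 0.05, and among heat shock genes 0 of 16 rose and 14 fell, with the same counts adjusted over the list alone (adjusted p = 1.28e-10).

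The lists too small for camera were counted against vehicle at the high doses. Of 4 metallothionein genes 3 rose and 0 fell with wortmannin, 1 rose and 0 fell with PT high, 1 rose and 0 fell with SR high and 1 rose and 0 fell with CR high. Of 3 targets of the xenobiotic receptors PXR and CAR 2 rose and 0 fell with wortmannin, 1 rose and 0 fell with ZR high, 1 rose and 1 fell with SR high and 0 rose and 1 fell with CR high. Of 2 blood cell markers 1 rose and 0 fell with wortmannin, 1 rose and 0 fell with ZR high, 0 rose and 1 fell with SR high and 1 rose and 1 fell with CR high, and of 4 fibroblast and endothelial markers 1 rose and 0 fell with wortmannin, 1 rose and 0 fell with SR high and 1 rose and 1 fell with CR high. Only comparisons with a called member are given. Of 5 intestinal markers, 1 rose with wortmannin, 1 rose with SR, and 1 rose and 2 fell with CR, with no camera call.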
